A study of Mus musculus with 6 samples.

How the data were processed

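The series held polyadenylated RNA from 3 peritoneal EHE tumours and 3 livers of C57BL6 mice. Per the labels' protocols, tissues were kept frozen, total RNA was isolated with a Qiagen RNeasy kit, and libraries were made with the DNBSeq protocol at BGI. Reads were aligned with HISAT2 2.1.0 to mm10 and FPKM values were made with Cufflinks, per the submitters' processing notes. The deposited count table held whole-number counts per Ensembl gene for 55401 genes in all 6 libraries. The counting tool, its annotation and its handling of strand and of reads shared between paralogs are not given in the sources used here, so values of multigene families, overlapping genes and antisense genes are uncertain. Even numbers made up 55.0% to 70.7% of values from 1 to 10 counts, so a fragment may have been counted by both mates, and counting intervals and floors are then too narrow. The deposited FPKM values, 1 file per library, were used only for an alternative. Between 289 and 470 genes per library had 100 or more counts and an FPKM of 0, so a listed FPKM of 0 can be a failed estimate. For 213 genes of the count table no FPKM value was used here, and their names came from the reference table. The other 55188 names came from the files. Of 53 repeated FPKM identifiers the row with the highest mean was kept. Coordinates are those of GENCODE mouse release 21 on GRCm38, the assembly of mm10.

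Samples were grouped by their titles. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (17387 of 55401), libraries were scaled by TMM, and a quasi-likelihood model with robust settings compared tumours with livers without covariates. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values are TMM-scaled. A gene with 0 counts in a group has a bound from 3 counts per library in place of a fold change, and a gene with 1 to 3 counts in a group a ratio with a 95% exact binomial interval. Those bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 0.393. Libraries of a group were checked for duplicates: chi-square per degree of freedom between replicate pairs was 105 or more, so none were counted as 1 sample.

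Before the data were examined, 49 gene lists (924 entries, 923 matched) were fixed for functions of endothelium, EHE signalling, cell division, matrix, liver and the other cell types a peritoneal tumour or liver could hold. The 47 lists with 5 or more tested members were compared with other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance one way, were run beside it. Named genes were chosen by a rule fixed then: both fusion partners, the 5 largest rises and 5 largest falls among called genes of 10 or more CPM without overlap between groups, and for each list the leading called members with 1 or more CPM in the majority direction (2 for lists of the main functions and cell types, with the leading member called in the other direction, and 1 for the other lists). This gave 91 genes, some of which are not reported here. Alternatives fixed then were RLE size factors, library totals alone, scaling without the 100 most abundant genes, no low-count filter, 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a 2-fold change, a replicate block, leaving out each library, and limma with a trend on log2(FPKM + 1) for genes at 1 or more in 3 libraries. Leaving out libraries 2 of both groups, and treating FPKM values of 0 at 100 or more counts as missing, were chosen after seeing the data.

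The tests were run on simulated counts over 16949 genes for the tumour and liver comparison, with the library sizes and dispersions of these libraries. Each gene had a single mean pooled over tumours and livers. The 200 changed genes were drawn from the more abundant ones, so the shares recovered do not describe genes at low counts. With edgeR, 65% of genes changed 4-fold and 2% of those changed 2-fold were called, with 4 unchanged genes called. Limma-voom recovered 61% and 2% with 2 unchanged genes called, and DESeq2 94% and 30% with 81 unchanged genes called. Limma on log2(value + 1), over 14706 genes, recovered 69% and 4% with 7 unchanged genes called. Median absolute fitted log2 fold changes of all changed genes, called or not, were 2.07 and 1.00 with edgeR. A list of raised genes was called and none of 40 unchanged lists were, with each tool. Simulated genes varied independently, while estimated correlations within the real lists reached 0.962 (skeletal muscle). The simulation therefore does not measure false list calls among correlated genes.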

Results

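Epithelioid hemangioendothelioma (EHE) is a cancer of endothelial cells that is commonly defined by a fusion of WWTR1, which encodes the transcriptional co-activator TAZ, with CAMTA1. The series held RNA sequencing of 6 C57BL6 mouse tissue samples in 2 groups, 3 EHE tumours from the peritoneal surface and 3 livers. Libraries of polyadenylated RNA gave 40277346, 38068941 and 38468030 counts in tumours 1 to 3 and 39072036, 33881392 and 39600125 in livers 1 to 3. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

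The libraries of each group resembled one another, with correlations of log2 CPM (counts scaled to a common library size) across genes from 0.943 to 0.975 among tumours, from 0.959 to 0.976 among livers and from 0.526 to 0.544 between the groups. Genes are not independent replicates, so these coefficients describe the libraries only. Albumin, the main plasma protein made by the liver, took 8.90%, 8.19% and 11.1% of the counts of livers 1 to 3. The 10 most abundant genes held 21.2% ± 1.41 of counts in livers and 6.58% ± 2.39 in tumours (SD, n = 3). Liver 2 stood apart in having counts for 33274 genes, against 19767 in liver 1 and 19001 in liver 3, and 17034 of its genes lay at 1 to 10 counts.

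**Figure D1:**
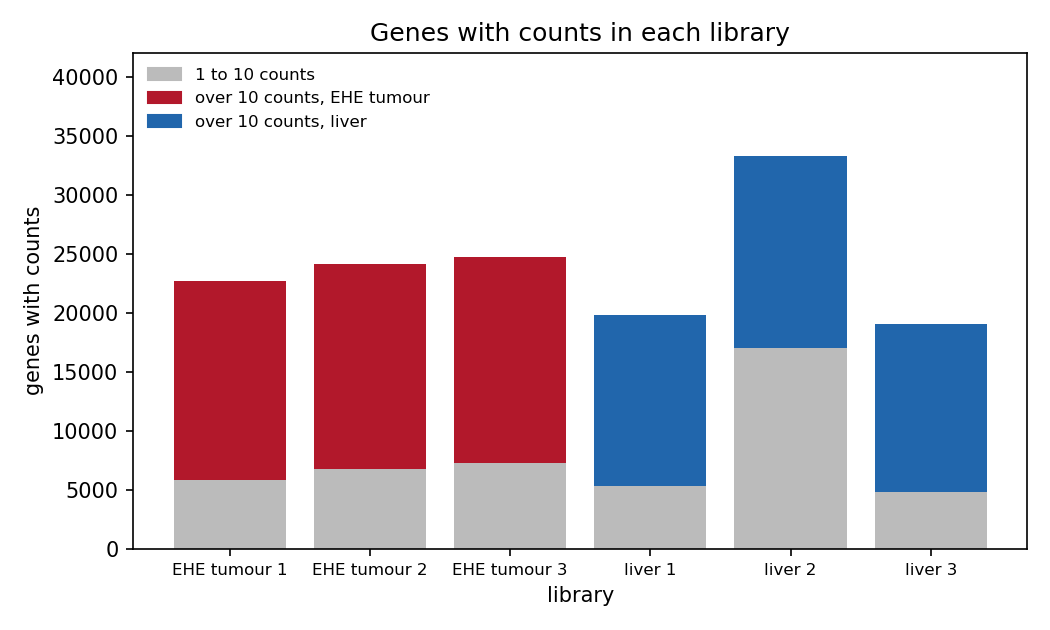
Number of genes with counts (vertical axis) in each of the 6 libraries (horizontal axis), split into genes at 1 to 10 counts (grey) and genes above that (red for EHE tumours, blue for livers). Liver 2 has 33274 genes with counts, of which 17034 lie at 1 to 10 counts, more than any other library.

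The only comparison in the design set the tumours against liver. Tumour state and tissue differ together in it, so no difference below can be assigned to 1 of them. In tumours 27 of 30 vascular endothelial genes, 25 of 25 mitosis genes, 26 of 30 collagen and matrix genes and 20 of 21 matrix proteases and inhibitors rose. Of 21 YAP/TAZ targets 12 rose, 2 fell and 7 did not pass. These 5 lists were called by camera, and each call was lost with an estimated correlation (adjusted p from 0.134 to 0.503). All 28 genes of plasma proteins made by hepatocytes and all 27 drug metabolism genes fell. Of 17387 genes tested with edgeR's quasi-likelihood test, 5137 were higher and 4982 were lower in tumours at an adjusted p under 0.05, and 7268 did not pass. A change of at least 2-fold was fitted for 4440 of the higher and 3971 of the lower genes. The values of the groups did not overlap for 11851 genes (68.2%), against 10% by chance with 3 samples in each group. The largest rises were in skeletal muscle genes, among them Acta1 (skeletal actin) and Myh1 (a fast myosin heavy chain). The largest falls were in Hpd (tyrosine breakdown), Cyp2d26 (a cytochrome P450), Serpina6 (corticosteroid-binding globulin), Rdh7 (retinol dehydrogenase) and Apoa5 (an apolipoprotein), each with 0 counts in all 3 tumours. With a floor of 3 counts per library, Hpd was at least 69923-fold lower, Cyp2d26 at least 43255-fold and Serpina6 at least 37259-fold lower in tumours, bounds that cover counting error only.

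These counts depend on how libraries are scaled. TMM factors were 1.52, 1.54 and 1.62 in tumours and 0.63, 0.68 and 0.61 in livers, and the median log2 fold change of all genes was 0.10. Scaling by library totals alone moved that median by 1.28 on the log2 scale, to 1.38, and gave 10688 higher and 2172 lower genes, so that 83.1% of calls were higher in place of 50.8%. Limma on log2(FPKM + 1) gave 8613 higher and 2031 lower genes (80.9% higher). Such a shift moves all genes by about the same amount, so it changes how many members of a list rise or fall, while camera compares a list with other genes. Fold changes are therefore given relative to the TMM scaling, and lists whose direction turned under another scaling are named as such.

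Both fusion partners were higher in tumours, Camta1 by far more than Wwtr1. Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910, GRCm38) had 45.7 ± 4.64 CPM in tumours and 26.9 ± 3.23 in livers (SD, n = 3 in each group), a log2 fold change of 0.77 (SE 0.16, edgeR adjusted p = 0.00612). Camta1 (ENSMUSG00000014592, chromosome 4, 150917322 to 151861876), a calmodulin-binding transcription activator, had 174 ± 54.7 CPM in tumours and 7.15 ± 1.58 in livers, a log2 fold change of 4.61 (SE 0.33, edgeR adjusted p = 4.61e-05). All 3 tumours exceeded all 3 livers for each gene, and the groups did not overlap for any gene given a fold change below. The Wwtr1 change did not pass a test against a 2-fold change (adjusted p = 0.978, alternatives from 6.93e-05 to 0.978). Counts per gene cannot separate fusion transcripts from transcripts of the native genes.

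Of a published list of 22 YAP/TAZ targets, 21 were tested, 12 rose, 2 fell and 7 did not pass. Adjusted over the list alone, 14 were called. The list lay above other genes with a median log2 fold change of 2.48 (camera adjusted p = 0.000168, adjusted p = 0.291 with an estimated correlation). Ptpn14, a phosphatase that binds YAP, rose by 6.70 (SE 0.49) and Ccn1, a secreted matricellular protein, by 5.13 (SE 0.41) on the log2 scale, while Nt5e (CD73) fell by 3.49 (SE 0.41). Of 22 Hippo pathway components, 14 rose and 2 fell (18 called adjusted over the list alone), with a median of 1.51 (camera adjusted p = 0.00335, adjusted p = 0.464 with an estimated correlation). Vgll3, a TEAD cofactor, rose by 7.08 (SE 0.69; 8.19 without liver 1) and Tead4 by 5.31 (SE 0.55; 6.08 without liver 2), and Wwc1, an upstream adaptor also called Kibra, fell by 6.90 (SE 0.27). For each of the 29 lists called here, the p with an estimated correlation was the highest over the alternatives tried.

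Vascular endothelial genes rose together. Of 30 tested, 27 rose and none fell past the threshold over all genes tested, and adjusted over the list alone 28 were called (27 higher, 1 lower). Their median log2 fold change was 3.91 (camera adjusted p = 2.2e-12, adjusted p = 0.134 with an estimated correlation). Podxl, a sialomucin of the endothelial surface, had 1304 ± 680.1 CPM in tumours and 6.85 ± 2.14 in livers, and Ecscr, an endothelial membrane protein, had 221 ± 70.4 and 3.05 ± 0.255 (SD, n = 3). Genes of liver sinusoidal endothelium went the other way, with 10 of 18 falling and 2 rising (12 called adjusted over the list alone), and a median of -2.13 (camera adjusted p = 0.00314, adjusted p = 0.432 with an estimated correlation). With library totals alone 8 rose and 8 fell, and the list kept its call as lower than other genes. Clec4g, a lectin of these cells, had 0.275 ± 0.0144 CPM in tumours and 58.3 ± 11.9 in livers, and Aass, a lysine breakdown enzyme that hepatocytes also make, fell by 10.99 (SE 0.81), while the scavenger receptor Stab1 rose by 2.79 (SE 0.44). Of 9 lymphatic endothelial genes 7 rose and 2 fell (9 called adjusted over the list alone), though the list was not called (camera adjusted p = 0.0569). Leaving out any single library gave it a call, with adjusted p from 0.0145 without tumour 1 to 0.0459 without tumour 3 (alternatives from 0.000498 by fry to 0.298). Mmrn1, a lymphatic marker, rose by 9.07 (SE 0.51). Of 25 angiogenesis and Notch genes, 16 rose and 2 fell (18 called adjusted over the list alone), with a median of 2.96 (camera adjusted p = 0.000271, adjusted p = 0.254 with an estimated correlation), a call that limma on FPKM did not make (adjusted p = 0.0524, alternatives from 2.74e-09 to 0.254). Placental growth factor (Pgf) rose by 10.07 (SE 1.38) and the Notch ligand Jag2 by 8.78 (SE 0.76), and the chemokine Cxcl12 fell by 3.94 (SE 0.33). All liver counts of Pgf (5) and Jag2 (4) lay in liver 2, so the sizes of these rises rest on that library. Pgf had 160.0, 14.7 and 60.1 CPM in tumours 1 to 3, and its rise was 9.01 without tumour 1. The endothelial list summed to 8609, 4151 and 7189 CPM in tumours 1 to 3, lowest in the library with the most skeletal muscle transcripts.

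**Figure D2:**
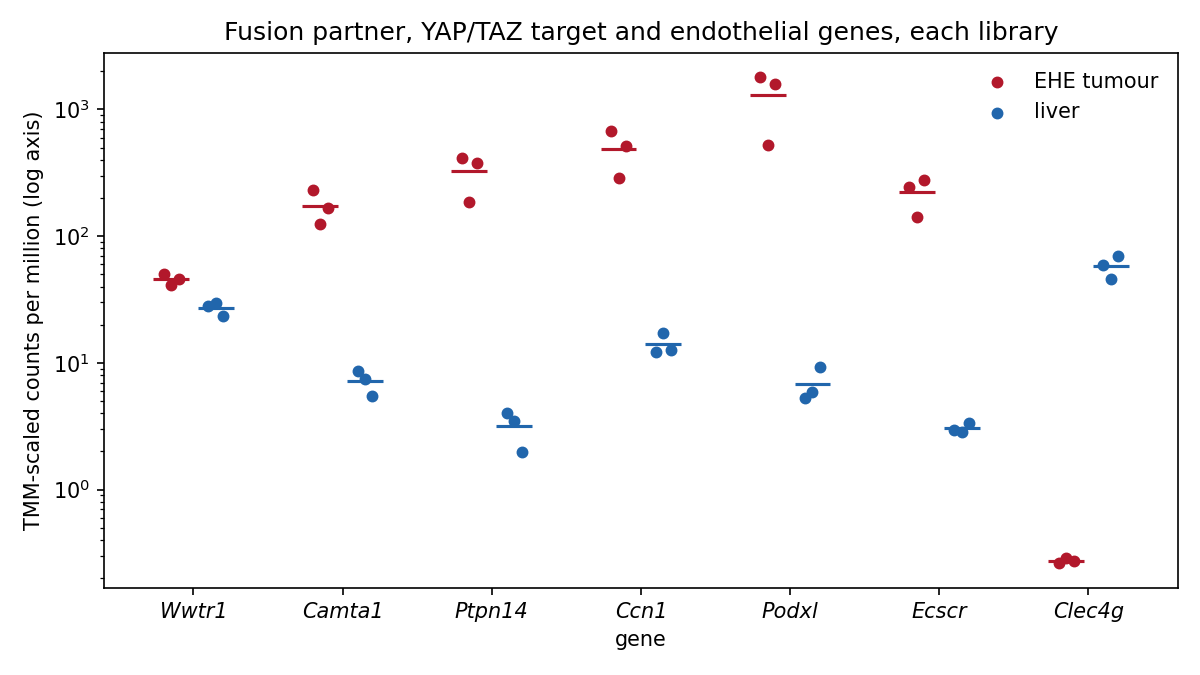
TMM-scaled CPM (vertical log axis) of 7 genes (horizontal axis) in each tumour (red) and liver (blue) library, with points for libraries and lines for means of 3. Camta1 (174 against 7.15 CPM) differs more than Wwtr1 (45.7 against 26.9 CPM), and Clec4g is the gene shown that is lower in tumours.

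All 25 genes of G2 phase and mitosis rose in tumours (25 called adjusted over the list alone), with a median of 3.61 (camera adjusted p = 7.36e-07, adjusted p = 0.503 with an estimated correlation). Less the median of all genes it was 3.50, and 2.82 without tumour 1. Bub1, a spindle checkpoint kinase, rose by 4.94 (SE 0.59) and Ccna2 (cyclin A2) by 4.64 (SE 0.49). Of 27 DNA replication and G1/S genes, 17 rose and 2 fell (19 called adjusted over the list alone), with a median of 1.26 (camera adjusted p = 0.012, adjusted p = 0.715 with an estimated correlation), a call that limma on FPKM did not make (adjusted p = 0.13, alternatives from 3.74e-05 to 0.715). Uhrf1 rose by 3.63 (SE 0.48) and E2f2 by 3.37 (SE 0.47). Of 24 genes of cyclin-dependent kinase inhibitors and p53, 17 rose and 2 fell (19 called adjusted over the list alone), with a median of 1.05 (camera adjusted p = 0.00904, adjusted p = 0.44 with an estimated correlation). Cdkn1a (p21) had 133 ± 34.8 CPM in tumours and 9.03 ± 4.39 in livers (SD, n = 3), Phlda3 rose by 3.77 (SE 0.42; 4.41 without liver 1) and the death receptor Fas fell by 2.78 (SE 0.52; -3.55 without tumour 2). Of 17 AP-1 and immediate early genes 16 rose (16 called adjusted over the list alone), with a median of 3.22 (camera adjusted p = 1.97e-08, adjusted p = 0.225 with an estimated correlation), and Ier3 rose by 5.69 (SE 0.25).

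Most extracellular matrix genes and their proteases were raised, though the summed collagen and matrix list overlapped between groups. That sum was 10389, 8367 and 5022 CPM in tumours 1 to 3 and 3249, 3394 and 5073 CPM in livers 1 to 3. Of 30 collagen and matrix genes, 26 rose and 1 fell (27 called adjusted over the list alone), with a median of 4.58 (camera adjusted p = 3.69e-11, adjusted p = 0.291 with an estimated correlation). The collagen crosslinking enzymes Loxl2 and Lox rose by 6.59 (SE 0.62; 5.998 without tumour 1) and 6.54 (SE 0.50; 7.17 without liver 2). Col14a1 fell by 1.68 (SE 0.36), a call lost with library totals alone (adjusted p = 0.311) and by limma on FPKM (adjusted p = 0.137, alternatives from 4.96e-09 to 0.311). Of 19 basement membrane genes, 15 rose and 2 fell (17 called adjusted over the list alone), with a median of 4.79 (camera adjusted p = 0.000217, adjusted p = 0.503 with an estimated correlation). The laminin chain gene Lama4 rose by 6.71 (SE 0.49), and Lama1, another laminin chain gene, fell by 5.33 (SE 0.80; -6.50 without tumour 1). Among 21 matrix proteases and inhibitors, 20 rose and 1 fell (21 called adjusted over the list alone), with a median of 4.86 (camera adjusted p = 6.18e-10, adjusted p = 0.134 with an estimated correlation), led by tissue plasminogen activator (Plat) at 9.58 (SE 0.83; 8.86 without tumour 1). Of 28 integrin and cytoskeleton genes, 23 rose (23 called adjusted over the list alone), with a median of 2.35 (camera adjusted p = 1.3e-07, adjusted p = 0.291 with an estimated correlation). Its leading members Flnc and Tpm2 are also muscle genes. Tpm2 had 178, 1479 and 313 CPM in tumours 1 to 3, Flnc had 719, 331 and 335 CPM, and the list summed to 11469, 10214 and 9161 CPM. Tpm2 rose by 6.91 (SE 1.00; 5.50 without tumour 2), and Flnc had 0, 16 and 2 counts in livers 1 to 3. Of 22 TGF-beta and BMP genes, 13 rose and 5 fell (19 called adjusted over the list alone), with a median of 1.59 (camera adjusted p = 0.0229, adjusted p = 0.455 with an estimated correlation), a call lost with library totals alone (adjusted p = 0.0547) and without libraries 2 of both groups (adjusted p = 0.0579, alternatives from 0.000327 to 0.455). Ltbp2 rose by 5.39 (SE 0.64; 4.72 without tumour 2). Of 17 fibroblast markers, 14 rose and 2 fell (16 called adjusted over the list alone), with a median of 4.24 (camera adjusted p = 0.00586, adjusted p = 0.541 with an estimated correlation), a call lost with library totals alone (adjusted p = 0.0821) and by limma on FPKM (adjusted p = 0.155, alternatives from 6.21e-06 to 0.541). Less the median of all genes the fibroblast median was 4.14, against 3.48 without liver 1 and 3.38 without liver 3. Thy1, which endothelial cells can also express, rose by 7.70 (SE 0.62). Pericyte and smooth muscle markers were not called as a list (camera adjusted p = 0.185), with 8 of 15 rising and 2 falling (11 called adjusted over the list alone), 5 rising and 4 falling without tumour 2, and 10 rising and none falling with library totals alone. With no low-count filter camera called that list higher (adjusted p = 0.0201, alternatives from 0.0201 to 0.75). Des (desmin, also in skeletal muscle) rose by 5.70 (SE 0.77; 4.63 without tumour 2).

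Liver functions were lower in tumours throughout the lists. All 28 genes of plasma proteins made by hepatocytes fell (28 called adjusted over the list alone), with a median of -15.09, or -15.97 without tumour 2 (camera adjusted p = 9.72e-33, adjusted p = 0.134 with an estimated correlation), and their sum was 338497, 262430 and 419098 CPM in livers 1 to 3 against 1125, 1663 and 1042 in tumours 1 to 3. Kng1 (kininogen) fell by 17.56 (SE 0.91), with 3, 2 and 0 counts in tumours 1 to 3. Apoc3 held 2 counts in all tumours together, both in tumour 3, a liver to tumour ratio of 231271 (95% exact interval 64021 to 1909690, counting error only). All 27 cytochrome P450 and drug metabolism genes fell (27 called adjusted over the list alone), with a median of -14.57, or -14.14 with the 7 members at 0 counts in all tumours set at their bound and -16.24 fitted without tumour 2 (camera adjusted p = 2.67e-49). Ugt2b36 and Cyp2c50, members of families whose paralogs can share reads, were at least 18509-fold and 18325-fold lower. All 21 urea cycle and amino acid genes fell (21 called adjusted over the list alone; median -10.29; camera adjusted p = 1.38e-34), including Otc, the ornithine transcarbamylase of the urea cycle, at least 14513-fold lower. All 16 tested bile acid and cholesterol genes fell (16 called adjusted over the list alone; median -10.14; camera adjusted p = 6.4e-23), including Slco1b2 at least 26827-fold and Akr1d1 at least 7443-fold lower. Apart from skeletal muscle, medians of the other lists with members at 0 counts in a group were the same with those members at their bound. The drug, urea and bile acid lists and the next kept their calls with an estimated correlation (adjusted p from 0.0375 to 0.0465). Of 14 hepatocyte transcription factors, 13 fell (13 called adjusted over the list alone), with a median of -7.73 (camera adjusted p = 1.23e-10), and Hnf4a had 0.0751 ± 0.103 CPM in tumours (2, 0 and 12 counts in tumours 1 to 3) and 973 ± 295 in livers (SD, n = 3).

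Of 22 fatty acid oxidation and peroxisome genes, 21 fell (21 called adjusted over the list alone), with a median of -3.88, or -4.70 without tumour 2 (camera adjusted p = 1.03e-08, adjusted p = 0.31 with an estimated correlation), led by Slc27a2 at -13.55 (SE 1.05; -15.43 without tumour 1) and Acaa1b at -10.21 (SE 0.91). Of 14 gluconeogenesis and glycogen genes, 11 fell and 2 rose (13 called adjusted over the list alone), with a median of -8.95 (camera adjusted p = 9.26e-07, adjusted p = 0.0738 with an estimated correlation). Fbp1 fell by 15.91 (SE 0.77), with 2, 0 and 4 counts in tumours 1 to 3. Of 14 acute-phase genes, 10 fell and 2 rose (13 called adjusted over the list alone), with a median of -8.95, or -10.32 without tumour 2 (camera adjusted p = 0.00461, adjusted p = 0.552 with an estimated correlation). Hamp (hepcidin) fell by 15.35 (SE 0.81; -14.74 without liver 1). Of 14 hepatic stellate cell markers, 11 fell and 1 rose (12 called adjusted over the list alone), with a median of -2.06 (camera adjusted p = 0.000215, adjusted p = 0.211 with an estimated correlation), and with library totals alone 6 fell and the list kept its call. Colec10 had 0 counts in tumours and was at least 979-fold lower. Bile duct markers were not called as a list (camera adjusted p = 0.805), with 1 of 11 rising and 3 falling (4 called adjusted over the list alone). Pkhd1 fell by 8.60 (SE 0.94), with all of its 4 tumour counts in tumour 2. Under library totals alone 6 of the bile duct markers rose and 2 fell.

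Immune markers differed between libraries of a group as well as between groups. Of 23 macrophage and monocyte markers, 13 rose and 1 fell (14 called adjusted over the list alone), with a median of 1.83, or 1.09 without tumour 2 (camera adjusted p = 0.0134, adjusted p = 0.683 with an estimated correlation). That call was lost with library totals alone (adjusted p = 0.105), by limma on FPKM (adjusted p = 0.274) and without the libraries numbered 2 of both groups (adjusted p = 0.0849), over alternatives from 0.000117 to 0.683, and 8 of its genes rose without liver 2 and 20 with library totals alone. The monocyte chemokines Ccl7 and Ccl2 rose by 5.33 (SE 0.37) and 4.98 (SE 0.27), and Arg1, also a urea cycle enzyme of hepatocytes, fell by 3.27 (SE 0.54; -4.03 without tumour 2). Kupffer cell markers, the liver's resident macrophages, were not called as a list (camera adjusted p = 0.0805) with 7 of 14 falling and 1 rising (8 called adjusted over the list alone). Clec4f fell by 12.19 (SE 0.79), with 0, 2 and 4 counts in tumours 1 to 3, and Cd207 fell by 5.68 (SE 1.21; -5.09 without tumour 1), with 0, 22 and 2 counts. Marco, also a macrophage receptor elsewhere, had 7.30, 3.90 and 32.2 CPM in livers 1 to 3. It rose by 3.80 (SE 0.90; 5.18 without liver 3), a call lost with no low-count filter (adjusted p = 0.104, alternatives from 3.72e-06 to 0.104). Without tumour 2, 9 Kupffer genes fell and the list was called lower (adjusted p = 0.0135), as it was without liver 2 (adjusted p = 0.0103). With library totals alone 3 rose and 5 fell, and the list was called lower (adjusted p = 0.012, alternatives from 0.000587 to 0.733). Of 22 T and NK cell markers 10 rose and 2 fell (11 called adjusted over the list alone; camera adjusted p = 0.23), including perforin (Prf1) at 5.03 (SE 0.71) and the checkpoint receptor Pdcd1 at 3.88 (SE 0.96; 5.33 without liver 1), while Zap70 fell by 3.46 (SE 0.49; -4.18 without tumour 2). Zap70 held 42.0, 32.5 and 33.1 of the list's 90.4, 61.3 and 56.1 CPM in livers 1 to 3. The cell source of these Zap70 transcripts was not tested. Without tumour 2 the T and NK cell list had 5 rising and 3 falling, against 16 and 1 with library totals alone. Of 15 dendritic cell and MHC class II genes 11 rose and none fell (11 called adjusted over the list alone; camera adjusted p = 0.0898), with 8 rising without tumour 2 and 5 without liver 2. The list was called higher without tumour 1 (adjusted p = 0.0421), tumour 3 (0.018) or liver 2 (0.0461), over alternatives from 0.00559 to 0.766. Its sum was 1011, 6139.7 and 834 CPM in tumours 1 to 3 and 643, 361 and 309.8 CPM in livers 1 to 3. Ciita, the class II transactivator, had 8.48, 62.5 and 6.94 CPM in tumours 1 to 3 and 2.72 ± 1.14 in livers (SD, n = 3), a log2 fold change of 3.26 (1.51 without tumour 2). Its edgeR adjusted p of 0.0216 became 0.0661, 0.0544 and 0.0716 without livers 1, 2 and 3, and the call was lost in 5 of 17 alternatives (from 0.00538 to 0.16). Of 16 B and plasma cell genes 4 rose and 1 fell (3 called adjusted over the list alone; camera adjusted p = 0.285), with 2 rising and 1 falling without tumour 2. Under library totals alone 12 of the 16 rose and none fell, and by limma on FPKM 10 of 13 rose and none fell. Iglc1, an immunoglobulin light chain constant region, had 7.14, 15.2 and 58.2 CPM in tumours 1 to 3. It rose by 3.46 (SE 0.83; 2.21 without tumour 3), a call lost by limma-voom (adjusted p = 0.0903) and with no low-count filter (adjusted p = 0.0893, alternatives from 1.1e-05 to 0.0903). Of 11 neutrophil genes 3 rose (3 called adjusted over the list alone; camera adjusted p = 0.66), including Il1r2 at 4.26 (SE 0.56; 4.88 without liver 1). The neutrophil list's median (0.13) and mean (-0.05) differed in sign. Its median was 0.63 without tumour 2 and turned negative without liver 2 (-0.999948, 12 genes tested), so its direction rests on single libraries. Liver 1 also stood apart, with a neutrophil sum of 154.6 CPM against 18.7 and 24.4 in livers 2 and 3. Tumours 1 to 3 had sums of 42.8, 42.3 and 53.8 CPM. Of 6 mast cell genes 3 rose (2 called adjusted over the list alone; camera adjusted p = 0.0789), including Gata2, also an endothelial factor, at 7.09 (SE 0.37). With tumour 3 or liver 1 left out that list was called (adjusted p = 0.0222 and 0.0338, alternatives from 0.00592 by fry to 0.503). Without tumour 2 or liver 2, 1 of its genes rose, against 5 with library totals alone.

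Of 27 interferon-stimulated genes, 14 fell and none rose past the threshold over all genes tested (13 called adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.0155, adjusted p = 0.698 with an estimated correlation). With library totals alone 6 rose and 7 fell, with a median of 0.34, and the list kept its call as lower than other genes. The call was lost by limma on FPKM (adjusted p = 0.185, alternatives from 9.97e-06 to 0.698). Without tumour 2, 20 fell. Oasl1 fell by 3.70 (SE 0.24) and Mx2 fell by 3.19 (SE 0.42).

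Glycolytic and hypoxia genes rose, with 16 of 23 higher and 3 lower (20 called adjusted over the list alone), and a median of 3.10 (camera adjusted p = 2.13e-05, adjusted p = 0.31 with an estimated correlation). The lactate carrier Slc16a3 rose by 6.64 (SE 0.28), Pdk1 fell by 2.03 (SE 0.24), and Car9 rose by 4.93 (SE 1.19; 3.88 without tumour 1), a call lost by limma-voom (adjusted p = 0.0961) and with no low-count filter (adjusted p = 0.0983, alternatives from 1.03e-05 to 0.0983). Of 23 nuclear respiratory chain genes 22 fell and none rose (22 called adjusted over the list alone), with a median of -1.42 (camera adjusted p = 0.00645, adjusted p = 0.733 with an estimated correlation), led by Ndufa4 at -2.33 (SE 0.40). With library totals alone 1 of these fell and the list kept its call as lower than other genes, and the call was lost by limma on FPKM (adjusted p = 0.133, alternatives from 3.99e-08 to 0.733). Of 13 mitochondrially encoded genes 6 fell (3 called adjusted over the list alone), and the list was not called (camera adjusted p = 0.139). They had a median of -1.42, or -2.11 without tumour 2 and -1.12 without liver 2. All 13 fell without tumour 2, when the list was called (adjusted p = 0.0115, alternatives from 0.000338 to 0.799), 1 fell without liver 2 and none changed with library totals alone. The call of mt-Atp8, which fell by 1.96 (SE 0.49), was lost with library totals alone (adjusted p = 0.235, alternatives from 1.92e-06 to 0.235). Mitochondrial transcripts took 2.44%, 7.67% and 3.74% of counts in tumours 1 to 3 and 5.26%, 8.68% and 3.68% in livers 1 to 3. The ribosomal protein list did not differ from other genes, with 1 of 25 falling, none called adjusted over the list alone and a median of -0.08 (camera adjusted p = 0.946), and 21 rose with library totals alone. Its called member, Rps2, had a log2 fold change of -0.73 (SE 0.25, edgeR adjusted p = 0.0364) that lost its call when tumour 1 or 3 or any of the livers was left out (adjusted p = 0.0663, 0.105, 0.144, 0.0586 and 0.0756 in that order, alternatives from 0.00474 to 0.898) and was positive with library totals alone. Subunits of the ATAC histone acetyltransferase complex were not called as a list (camera adjusted p = 0.859), with 2 of 11 rising and 4 falling (5 called adjusted over the list alone), and 9 rose with library totals alone. Fry called the ATAC list lower (adjusted p = 0.0033, alternatives from 0.0033 to 0.968). Kat2b fell by 1.47 (SE 0.17), a call lost with library totals alone (adjusted p = 0.349) and by limma on FPKM (adjusted p = 0.254, alternatives from 4.02e-14 to 0.349). Of 20 receptor tyrosine kinases and ligands 6 rose and 8 fell (14 called adjusted over the list alone; camera adjusted p = 0.911), including Fgfr4 at -7.45 (SE 0.71; -8.67 without tumour 2). Their median (0.07) and camera's direction (lower) differed in sign, and 10 rose with library totals alone.

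Markers of other tissues showed that tumour samples held skeletal muscle transcripts. All 14 tested skeletal muscle genes rose (14 called adjusted over the list alone), with a median of 12.48, or 11.69 with the member at 0 counts in livers set at its bound (camera adjusted p = 2.89e-05, adjusted p = 0.503 with an estimated correlation). The fitted median was 10.83 without tumour 2 and 16.97 without liver 2. Fitted values depend on the prior count where livers hold 0 counts. The muscle list summed to 1980.5, 16017 and 3471 CPM in tumours 1 to 3 and to at most 3.34 CPM in a liver. Acta1 had 49314, 278101 and 79620 counts in tumours 1 to 3 and 1 count in all livers (liver 2), a ratio of 160975 (95% exact interval 28892 to 6358200). Mb (myoglobin) also had 1 count in all livers (liver 2), 46937 counts in tumour 2 against 4031 and 5759 in tumours 1 and 3, and a ratio of 22435 (interval 4026 to 886132). Myh1, Myot (myotilin) and Hspb7 had 0 counts in livers and were at least 2994-fold, 1046-fold and 1041-fold higher, calls that were lost with no low-count filter (adjusted p = 0.0792, 0.136 and 0.101, the highest over the alternatives, with lowest values of 1.74e-27, 2.27e-12 and 1.65e-22). Most of their counts lay in tumour 2 (47916, 18054 and 16374). Of 14 adipocyte genes 6 rose and 4 fell (11 called adjusted over the list alone; camera adjusted p = 0.549). Without tumour 2, 4 rose and 4 fell, with library totals alone 10 rose and 2 fell, and by limma on FPKM 8 of 12 rose and 3 fell. Cfd (adipsin) had 2 counts in all livers, both in liver 2, and a tumour to liver ratio of 2386 (interval 660.5 to 19707). Of 17 mesothelial genes 11 rose and 3 fell (15 called adjusted over the list alone; camera adjusted p = 0.162), including Aldh1a2 at 6.02 (SE 0.88; 7.18 without liver 2), and without liver 1 the list was called (adjusted p = 0.037, alternatives from 0.0184 to 0.766). The mesothelial sum went the other way, at 390, 467 and 365 CPM in tumours 1 to 3 and 594, 504 and 563 CPM in livers 1 to 3. Red cell genes summed to 3820.2, 942 and 5179.7 CPM in tumours 1 to 3 and 1841, 1072 and 980.2 CPM in livers 1 to 3, with 5 of 11 rising and 1 falling (6 called adjusted over the list alone; camera adjusted p = 0.547). Without tumour 2, 10 rose and the list was called (adjusted p = 0.0461, alternatives from 0.0276 to 0.97), and without liver 2, 1 rose and 1 fell. By library totals alone 10 rose and 1 fell. Epb42 rose by 2.96 (SE 0.81; 2.36 without tumour 3 and 3.55 without liver 2), a call lost without tumour 3 (adjusted p = 0.059), liver 1 (0.0653) or liver 3 (0.0569), over alternatives from 5.19e-05 to 0.0863. Epithelial genes had 3 of 10 rising and 3 falling (6 called adjusted over the list alone; camera adjusted p = 0.262), with Cldn3 at -5.12 (SE 0.72; -6.29 without tumour 2), and intestinal genes 1 of 6 rising and 2 falling (2 called adjusted over the list alone; camera adjusted p = 0.111). Both medians turned with library totals alone, from -0.67 to 0.60 and from -0.66 to 0.57, where the intestinal list was called lower than other genes (adjusted p = 0.0298, alternatives from 0.00792 by fry to 0.598). The intestinal median also turned without liver 2, to 1.17. The epithelial list was called lower by limma on FPKM, with 3 of 5 genes falling and none rising (adjusted p = 0.00521, alternatives from 0.003 by fry to 0.549). Fabp2, which the liver also expresses, had 0 counts in tumours and was at least 1507-fold lower. Of 15 exocrine pancreas genes only Rnase1 was tested, at 1.17 ± 0.788 CPM in tumours and 0.0722 ± 0.125 in livers (SD, n = 3; edgeR adjusted p = 0.0386). All of its 5 liver counts lay in liver 2. That call was lost without tumour 1 (0.0993), tumour 3 (0.0967), liver 1 (0.111) or liver 3 (0.102), over alternatives from 0.000417 to 0.122.

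**Figure D3:**
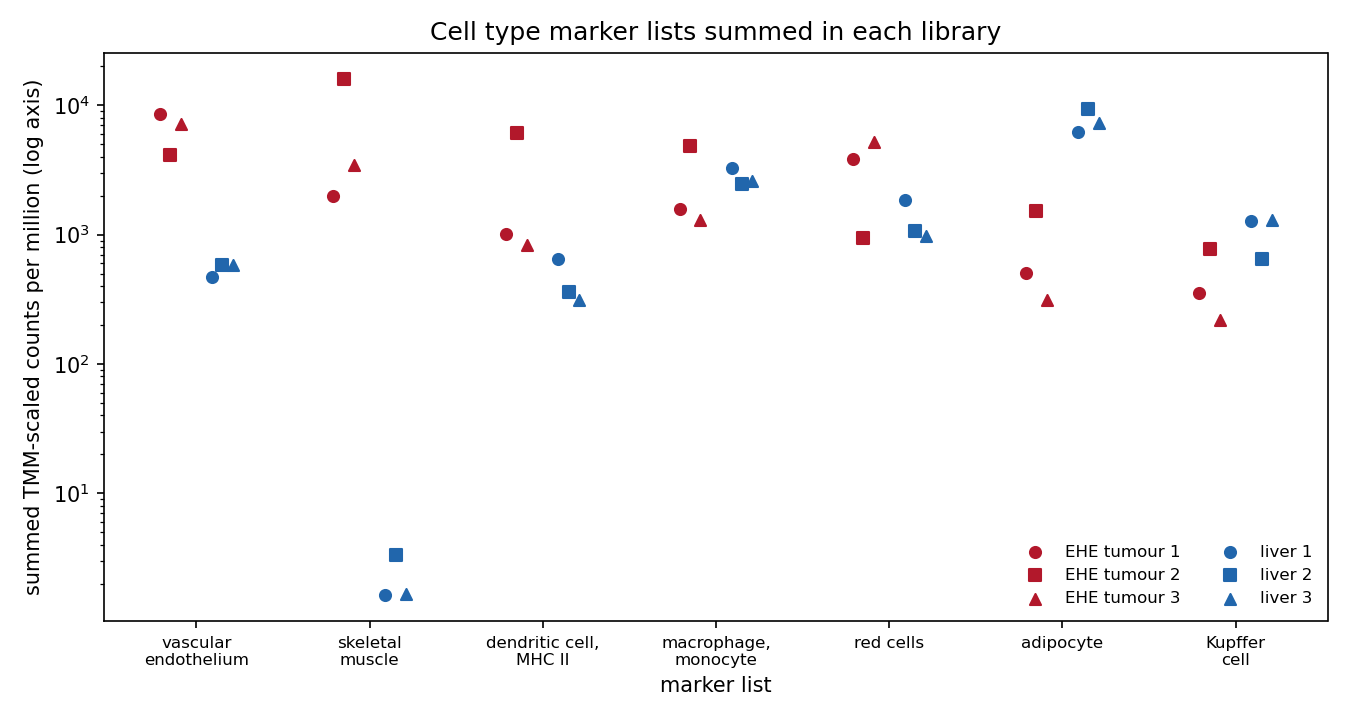
Summed TMM-scaled CPM (vertical log axis) of 7 marker lists (horizontal axis) in each library, red for tumours and blue for livers, with a marker shape for each library number. Tumour 2 holds the highest skeletal muscle (16017 CPM) and MHC class II sums and the lowest endothelial sum (4151 CPM) of the tumours, and the adipocyte and macrophage sums of livers include metabolic enzymes such as Arg1 that hepatocytes make.

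**Figure D4:**
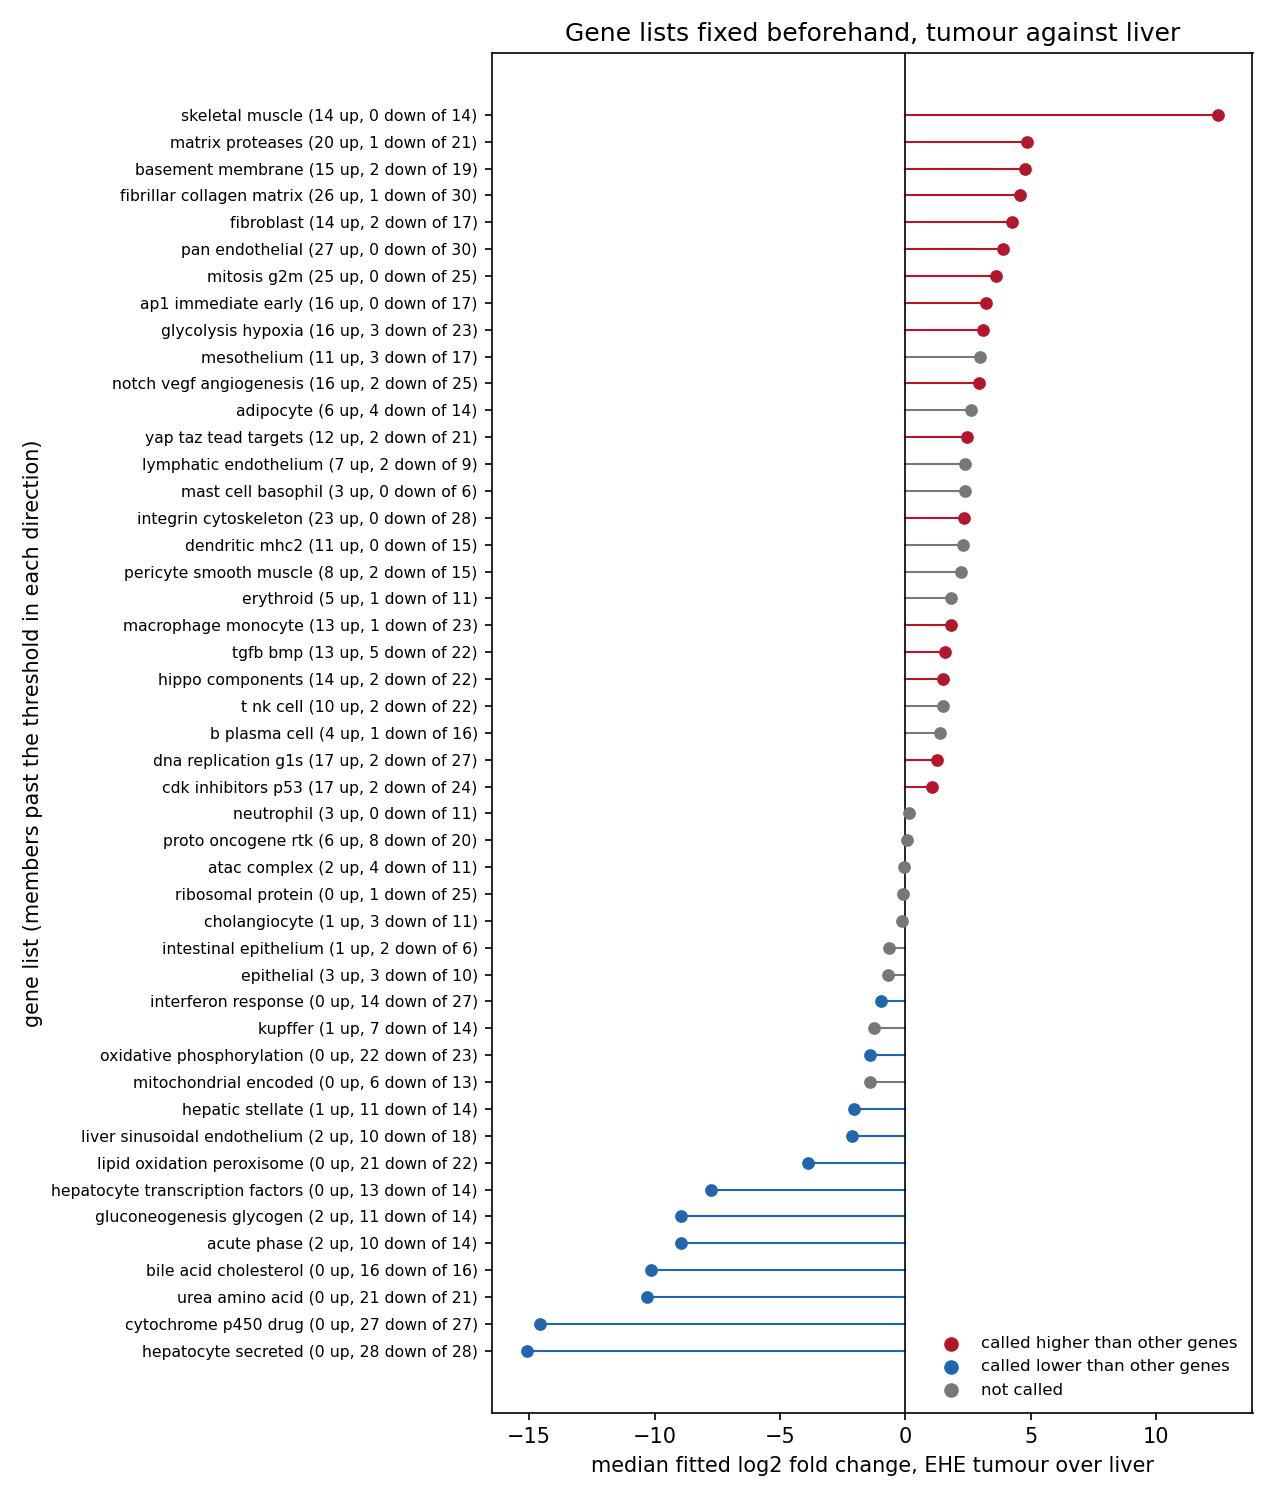
Median fitted log2 fold change (horizontal axis, tumour over liver, TMM scaling) of the 47 gene lists tested, one per row, with the number of members past the threshold in each direction. Red and blue lists were called higher or lower than other genes by camera (29 lists), grey ones were not, and the medians of the interferon, Kupffer, intestinal, epithelial, bile duct, ribosomal and ATAC lists turn positive with library totals alone, which shifts all genes by a median of 1.28.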

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

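Under the alternatives, 5137 higher and 4982 lower genes and 29 called lists became the following. Counts stayed within 1.5 times with RLE size factors, scaling without the 100 most abundant genes, both filters, DESeq2 and limma-voom. Leaving out each library in turn gave from 4201 to 5150 higher genes, from 4286 to 5178 lower genes and from 30 to 33 lists. Library totals alone gave 10688 higher and 2172 lower genes: 7309 of the 10119 called genes kept their direction and call, and 552 were called in the opposite direction, since this scaling shifts every gene by about the same amount. Limma on FPKM gave 8613 higher and 2031 lower genes among 13640 tested, with other values, scaling, filter and test together, or 8603 and 1984 with failed zeros missing, and the cause was not tested. The test against a 2-fold change, which asks for a larger effect, gave 3314 and 2916 genes and no list test. An estimated correlation left 4 of the 29 lists and fry called 35, and the cause was not tested. The fall of Rps2 reversed to 0.55 with library totals alone and to 0.36 with limma on FPKM, as deposited and with failed zeros missing (0.36), none of them past the threshold. Without libraries 2 of both groups 5740 genes were higher, 5062 lower and 31 lists called. Same-numbered tumours and livers deviated together by correlations of 0.019, 0.037 and -0.025. These values cannot tell whether equal numbers share an animal, since deviations within 2 different tissues need not follow the animal. With a replicate block 4516 genes were higher, 4574 lower and 33 lists called, and no sample correlated best with its own number. Of the 91 named genes, 77 were past the threshold in each alternative that gave a value, and 22 of the 29 lists were called in each alternative but the estimated correlation. Over all alternatives, values of named genes kept direction and side of the threshold 1579 times, lost the call 40 times and reversed 3 times, and those of lists kept both 801 times, lost the call 41 times and gained it 44 times. The alternatives for a series with normalized values alone were not run, as counts were used. Leaving out libraries 2 together and failed zeros as missing were chosen after seeing the data. In simulated data edgeR found 2% of 2-fold changes, but only 200 of 16949 genes changed there, so that share does not carry over to a comparison with 10119 called genes.

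With 3 samples against 3 there are 10 splits of the samples, too few for a share under 0.05. Of these, 1 gave as many higher genes as the 5137 observed and 1 as many lower genes as the 4982 observed, and the highest of the others was 0 by edgeR. At an unadjusted p under 0.05 the other splits had 26 to 266 genes, limma-voom called 0 and DESeq2 at most 44. Each of the other splits put tumours and livers into both groups, so the tissue difference widened the spread within groups. Low gene counts were thus built in, and these splits do not measure chance. For the 29 lists, 5 of the splits, the observed one included, called as many. The other splits called from 21 to 34 lists, so the number of lists called does not set the observed grouping apart. Each of the other splits still held unequal numbers of tumours and livers in a group. List calls there may thus come from the tissue difference, and they do not measure false list calls.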

Other observations

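The following tests were chosen only after the result was seen: that of tumour 2 alone, the share of liver 2 genes at 0 in tumours, and both tests on Camta1. Gene families grouped by symbol were not fixed beforehand, and 26 of 251 families were called by camera (7 higher, 19 lower in tumours), 1 of them with an estimated correlation (Cyp). The clustered protocadherin beta genes, adhesion molecules best known from neurons, were higher in tumours: 18 of 20 rose and none fell, with a median log2 fold change of 4.49 (camera adjusted p = 0.000183, adjusted p = 0.915 with an estimated correlation), and all 20 rose with library totals alone. They are paralogs, and how reads shared between paralogs were counted is not given in the sources used here, so the values of single members are uncertain. Semaphorins had 12 of 20 rising and 2 falling (median 3.10, camera adjusted p = 0.0346, adjusted p = 0.915 with an estimated correlation), and kinesins 21 of 35 rising and 3 falling (median 1.75, camera adjusted p = 0.0225, adjusted p = 0.915 with an estimated correlation).

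Proteins of the mitochondrial ribosome were lower, with 44 of 48 Mrpl genes and 25 of 29 Mrps genes falling and none rising (medians -1.30 and -1.47, camera adjusted p = 8.29e-06 and 0.000447, adjusted p = 0.915 for both with an estimated correlation). With library totals alone 7 Mrpl genes rose and 9 fell, and 4 Mrps genes rose and 7 fell, with medians of -0.01 and -0.19. All genes shift under that scaling by a median of 1.28, so these counts do not bear on the families relative to other genes. Peroxins, which build peroxisomes, fell in 16 of 16 genes (median -2.29, camera adjusted p = 3.79e-08, adjusted p = 0.623 with an estimated correlation), and in 13 of 16 with library totals alone. Major urinary proteins, near-identical copies made by the liver, fell in 18 of 18 genes (median -11.58, camera adjusted p = 8.42e-08, adjusted p = 0.789 with an estimated correlation).

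Skeletal muscle genes were present in every tumour, most in tumour 2. Skeletal muscle tissue within the tumour samples may be the source. A second list of 23 muscle genes, fixed before its values were seen, was higher in tumours for all 23. Its median ratio of tumour 2 to tumour 1 was 8.80, against 9.50 for the first list. Muscle genes would move together whatever their source, so this likeness does not tell muscle tissue from another source. Ckm, among the most abundant, had 102, 1035 and 171 CPM in tumours 1 to 3, and 1 gene of the first list and 3 of the second were at 1 CPM or more in livers. The embryonic and perinatal myosins Myh3 and Myh8 held at most 0.188% of the counts of 6 myosin heavy chain genes. This argues against an immature muscle programme as the main source of those counts, but adult myosins could mask a smaller one. Nor did tumour 2 alone carry the pattern, since 100% of the tested list was called without it (14 of 14), and muscle tissue stays open as the source.

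Liver 2 had the lowest total of the 6 libraries but the most genes with counts, so depth does not account for them. Genomic DNA in that library may account for them: silent olfactory receptor genes had 10.04 times the depth-scaled counts per kilobase of the mean of livers 1 and 3, were seen in 64.3% of 1103 genes against 3.08% and 2.45%, and their density lay within 1.16-fold of that of 2 other silent receptor families. Carry-over from tumour libraries is argued against as the only source. Of the 12993 genes with counts in liver 2 and none in livers 1 and 3, 60.8% had 0 counts in all tumours. Among all 33771 genes at 0 in livers 1 and 3 that share was larger (25567 genes), so some carry-over beside another source is not excluded. The ratio of liver 2 density between genes high and at 0 in tumours was 1.46 (95% bootstrap interval 1.33 to 1.59 over genes), which spans the bound of 1.5 set beforehand. No biological explanation was tested.

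Camta1 rose more than Wwtr1, although a fusion of the genes would give counts to both. Muscle in the samples is argued against as the source, since Camta1 in tumour 2 was 0.621 times the mean of tumours 1 and 3, while the muscle list was 5.88 times it. The rise per kilobase of annotated exon was 2.91 times larger for Camta1. A rise is the tumour mean less the liver mean (174 less 7.15 CPM for Camta1, 45.7 less 26.9 CPM for Wwtr1). Without that subtraction the ratio is much smaller, since tumour means of 174 and 45.7 CPM lie over exon lengths of 14570 and 4779 bases. The size of the ratio thus rests largely on the liver levels subtracted, and tumour cells need not keep the Wwtr1 level of liver. The part of each gene within the fusion is not given by counts per gene, so fusion transcripts with unequal parts cannot be told apart from native Camta1 transcripts. A higher native level in endothelial tumour cells than in hepatocytes stays open, as the tissues of the design differ.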
